A study of Homo sapiens with 4 samples.

How the data were processed

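RNA was sequenced from 4 cultures of A549 cells, 1 library per group: a line carrying a control short hairpin RNA and a line with METTL16 knocked down by a short hairpin RNA, each kept for 2 h in complete medium or in medium for amino acid starvation. The genotype label of the control libraries reads WT. Cells had been grown in DMEM with 10% serum and 1% antibiotics at 37 °C and 5% CO2. Total RNA was isolated with Trizol and sequenced on a NovaSeq instrument. The composition of the starvation medium, its serum included, and the enrichment or depletion step of the libraries are not given in the sources used here.

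The authors deposited whole-number counts of reads per gene for 60648 genes, with gene lengths, and the sum of each column gives its depth. The authors also deposited TPM values (length-scaled transcript abundances) for 19955 protein-coding genes; these values equal the counts divided by gene length and scaled by their sum over all genes of the count table. The submitters name cutadapt 2.8, Bowtie2 2.2.5, STAR 2.7.5c, featureCounts 2.0.1 and edgeR 3.40.2, with the genome GRCh38. The role of each tool, the annotation release, the strand setting and any filter are not given in the sources used here. The count row of 1 gene, ANK2, is broken over 3 lines and was left out. The name of the starved knockdown column differs by 1 letter from the label of its sample and was matched by elimination.

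Counts were analysed with R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1; figures were drawn with matplotlib 3.10.9. Library totals were scaled with the trimmed mean of M values (TMM), and log2 ratios of library-scaled counts (CPM) used a prior count of 2. The 14859 genes with a mean CPM of at least 1 were tested. Coordinates are from GENCODE release 29 on GRCh38.

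Totals were 503585 counts in the control line in complete medium, 537558 in the control line starved, 775676 in the knockdown line in complete medium and 465303 in the knockdown line starved. A gene with 0 counts could therefore lie at up to 5.96, 5.58, 3.87 and 6.45 CPM in these libraries, from a floor of 3 counts per library. Intervals of a fold between 2 libraries are 95% exact conditional (Clopper-Pearson) intervals. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules and no group has a replicate.

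With 1 library per group, no p-value was computed for a single pair of libraries. A size rule was used instead: a log2 ratio of at least 1 in either direction with a counting interval that excludes a ratio of 1. The size rule was applied to starvation in each line and to the knockdown in each medium. Both pairs of a comparison share no library, so the genes past the rule in the same direction in both were counted beside the number expected if the pairs were independent. Over all 4 libraries, edgeR's quasi-likelihood test was fitted with genotype and medium as additive terms, which leaves 1 residual degree of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. In that fit the residual is the difference between both lines' responses, and its size was pooled over genes (the median prior degrees of freedom were infinite), so a gene that responds in 1 line alone can be called. The difference itself was described with the size rule, with an interval from a normal approximation on log counts plus 0.5, and was not tested. Words for a change of a gene are used for genes called by the additive test. SE is an approximate standard error of that test's log2 fold change. It is the absolute log2 fold change divided by the square root of the test's F statistic, and is least reliable for genes with 0 counts.

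Gene lists numbered 39: ATF4 and integrated stress response targets, amino acid transporters, cytosolic aminoacyl tRNA synthetases, serine, glycine and one-carbon enzymes, the methionine and S-adenosylmethionine cycle, m6A machinery, the extrinsic death receptor pathway, the BCL2 family, p53 targets, autophagy, lysosome (TFEB) targets, immediate early genes, NF-kB targets, FOXO targets, cholesterol (SREBP2) targets, fatty acid synthesis, glycolysis, hypoxia targets, NRF2 targets, the unfolded protein response, heat shock, ribosomal proteins, ribosome biogenesis, translation factors, the MTORC1 pathway, U6-associated spliceosome proteins, SR proteins and splicing kinases, S phase, G2 and M phase, replication-dependent histones, interferon-stimulated genes, mesenchymal genes, epithelial and alveolar genes, mitochondrially encoded genes, nuclear genes of oxidative phosphorylation, and markers of fibroblasts, immune cells, endothelial cells and kidney (HEK293) cells. At least 5 genes were tested in 37 of them, all but the immune and endothelial markers. Each list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins. Percentiles of 148 lists and comparisons were computed; 34 lay at or beyond 2.5 or 97.5, where chance gives 7.4. They describe these libraries, not replicated cultures, and genes of a list are not independent. Adjusted p-values were also computed over each list alone.

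Genes were named by a rule: METTL16, MAT2A, TNFRSF10A, TNFRSF10B, FAS, CASP8, ATF4, DDIT3 and ASNS always; the 10 highest and 10 lowest mean ratios among genes of mean CPM 5 or more past the size rule in both pairs, for starvation and for the knockdown; the 8 largest and 8 smallest differences between the starvation responses; and up to 4 members per list with the largest mean ratio in either direction. Genes withheld for evaluation are left out of the text although this rule or the additive test selects them, and they stay in the counts. Pseudogene, readthrough and clone names were passed over. The lists, the rules for calling and naming genes, the tests for an effect of starvation or knockdown and most alternatives were fixed before the data were examined. Other genes called by the additive test, list members outside the rule, and the sums over RNA classes were chosen after their values were seen.

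Alternatives covered DESeq2 size factors, total counts, the deposited TPM with a pseudocount of 0.1, other filters, other thresholds, a prior count of 0.5, DESeq2 and limma-voom in place of edgeR, a fit without the block, and random lists not matched on expression. Counts thinned to the smallest total, an interval widened by the fitted dispersion, and total counts in edgeR were added after the data were seen. The additive test was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. The changed genes were drawn from genes of mean CPM 20 or more, so recovery at lower expression was not simulated. The test found 16% and 83% of them for a starvation effect and 9% and 85% for a knockdown effect. In each, 4 calls fell among 14659 genes not changed. Every gene was given the common dispersion of the additive fit, so these calls do not cover errors from genes that vary more. The size rule made 713, 743, 717 and 696 calls among genes not changed in the same simulation, for starvation in the control line, starvation in the knockdown line, the knockdown in complete medium and the knockdown under starvation. Replicates could not be left out in turn and sample labels could not be permuted, since each group is 1 library.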

Results

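A549 is an established line of human lung adenocarcinoma cells. RNA levels were compared between a control line and a line with METTL16 knocked down, each in complete medium and after 2 h of amino acid starvation. The series asks how METTL16 affects cell death, and the extrinsic death receptors in particular, when nutrients are withdrawn. The 4 groups hold 1 library each, so no ratio of a single pair of libraries has a replicate error; ranges in parentheses are 95% counting intervals. Totals ran from 465303 counts in the starved knockdown library to 775676 in the knockdown library in complete medium, with 503585 and 537558 counts in the control libraries in complete medium and starved. Between 13761 and 15281 genes had a count in a library.

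METTL16 is an RNA methyltransferase that places m6A on U6 small nuclear RNA and on hairpins of the MAT2A message. METTL16 (ENSG00000127804.13, chromosome 17, 2405562 to 2511891) stood at 64.4 CPM in the control line and 26.5 CPM in the knockdown line in complete medium, from 34 and 19 counts. Under starvation METTL16 stood at 78.5 and 19.5 CPM, from 44 and 9 counts. The METTL16 level of the knockdown line was thus 0.412 (0.222 to 0.743) of the control level in complete medium and 0.249 (0.107 to 0.516) under starvation. Past the size rule in both media, METTL16 had an adjusted p of 0.057 in the additive test over both media (log2 fold change -1.60, SE 0.45), just above the threshold. MAT2A, the S-adenosylmethionine synthetase whose message METTL16 binds, was at 0.732 (0.587 to 0.915) of the control level in complete medium and 0.607 (0.456 to 0.804) under starvation, with an adjusted p of 0.587. The 26 tested genes of the m6A machinery had median knockdown ratios of 0.01 and -0.05 (log2), and adjusted over the list alone METTL16 was the 1 gene that fell.

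The messages of TNFRSF10A, TNFRSF10B and FAS had starvation ratios below 1 in both lines, without passing the test over all genes. TNFRSF10B, which encodes the TRAIL receptor DR5, was at 0.585 (0.454 to 0.751) of its level in complete medium in the control line and at 0.590 (0.444 to 0.776) in the knockdown line (adjusted p 0.308). TNFRSF10A, which encodes DR4, was at 0.712 (0.432 to 1.16) and 0.517 (0.274 to 0.927), and FAS, the receptor of FAS ligand, at 0.392 (0.167 to 0.851) and 0.575 (0.248 to 1.23). TNFRSF21, the gene of the death receptor DR6, had log2 ratios of 0.22 and -0.17. CASP8, the initiator caspase of this pathway, was at 1.18 (0.514 to 2.75) and 0.998 (0.381 to 2.48) on 9 to 15 counts per library. Against the control line, TNFRSF10B in the knockdown line was at 0.837 (0.677 to 1.04) in complete medium and 0.845 (0.618 to 1.15) under starvation, and TNFRSF10A at 0.863 (0.557 to 1.34) and 0.627 (0.320 to 1.18), so both intervals of each include 1. Of the 21 tested genes of the extrinsic death receptor list, BIRC3, an inhibitor of apoptosis, rose after starvation, none fell and 20 were not called; adjusted over the list alone, BIRC3 rose and TNFRSF10B fell, 1 gene each. The list's median starvation ratio was -0.08 in the control line and -0.44 in the knockdown line, at percentiles 27.0 and 2.25 of random lists. Its median knockdown ratio was 0.10 in complete medium and 0.22 under starvation, signs that turned with the deposited TPM and, in complete medium, with total counts.

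After 2 h of starvation some NF-kB targets and immediate early genes rose, together with PIM1 and PROC, which belong to neither list. PIM1, a kinase gene induced by cytokine signals, rose 6.0-fold (2.83 to 14.6) in the control line and 6.10-fold (3.35 to 11.9) in the knockdown line. ZFP36, which encodes the mRNA-destabilizing protein tristetraprolin, rose 3.90-fold (2.69 to 5.77) and 4.32-fold (3.06 to 6.19). KLF6, a zinc finger transcription factor gene, rose 3.22-fold (1.91 to 5.69) and 4.43-fold (2.99 to 6.72), and CXCL8, the gene of the neutrophil chemokine interleukin 8, 2.84-fold (2.21 to 3.67) and 4.06-fold (3.31 to 5.01). PROC (ENSG00000115718.18, chromosome 2, 127418427 to 127429246), the gene of the anticoagulant protein C, had the highest mean ratio of the genes named by the size rule, 9.73-fold (4.91 to 21.9) in the control line and 4.30-fold (2.61 to 7.36) in the knockdown line. In the additive test the log2 fold changes were 2.60 (SE 0.39, adjusted p 4.86e-08) for PROC, 2.58 (SE 0.44, 5.06e-06) for PIM1, 2.03 (SE 0.31, 6.05e-08) for ZFP36, 1.94 (SE 0.35, 3.34e-05) for KLF6 and 1.77 (SE 0.25, 9.72e-09) for CXCL8.

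Of the 24 tested NF-kB targets, 5 rose after starvation, none fell and 19 were not called; adjusted over the list alone, 8 rose. Beside CXCL8 and BIRC3, the risen members were IL6, the interleukin 6 gene (log2 fold change 1.89, SE 0.46), TNFAIP3, the gene of the NF-kB inhibitor A20 (1.89, SE 0.40), and CXCL2, a neutrophil chemokine gene (1.42, SE 0.34). The list's median log2 ratio was 0.69 in the control line and 0.49 in the knockdown line, at percentiles 100 and 99.99 of matched random lists, and positive with every scaling tried. Immediate early genes, 31 tested, had medians of 0.68 and 0.22, at percentiles 100 and 98.6 (96.52 in the knockdown line against lists not matched on expression), also positive with every scaling, and 17 of the 31 were positive in both lines. ZFP36, KLF6 and EGR1 rose among them and 28 were not called; adjusted over the list alone, 7 rose. EGR1, an early growth response transcription factor gene, rested on the control line: it had 2 and 42 counts there, a 19.8-fold ratio (5.14 to 169), and 1 count in each library of the knockdown line. FOS, a subunit gene of the AP-1 factor, had 0 and 16 counts in the control line, at least 5.02-fold higher after starvation, and 5 and 4 counts in the knockdown line (adjusted p 0.642). JUNB, another AP-1 gene, had log2 ratios of 1.85 and 0.38 (adjusted p 0.344 over all genes), and was among the 7 that passed over the list alone.

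The 28 risen genes included single members of other lists. EEF2, the ribosomal translocation factor, rose by 1.08 on the log2 scale (SE 0.19, adjusted p 9.3e-06), and was the 1 called member of the 29 translation factors, 2 when adjusted over the list alone. FASN, the fatty acid synthase gene, rose by 1.07 (SE 0.21, adjusted p 0.000323), while SCD, the stearoyl-CoA desaturase gene, fell by 0.59 (SE 0.15, adjusted p 0.0361); the other 11 tested fatty acid synthesis genes were not called. KRT7, an epithelial keratin gene, rose by 0.76 (SE 0.20), the 1 called gene of 12 epithelial and alveolar genes. EEF1A2, ID1, ZFP36L1, YBX3 and GOLGA4 rose too, by 1.15, 1.32, 1.17, 1.17 and 1.27. MALAT1, a nuclear long noncoding RNA, rose by 0.99 (SE 0.17, adjusted p 9.3e-06), as did 7 genes and variants of U1 small nuclear RNA, whose near-identical copies cannot be separated by counts alone.

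Of the 28 genes that fell after starvation, 6 have an annotated exon that overlaps a nuclear tRNA gene, against 24 of 14769 tested genes. Among the 28 risen genes, 0 have such an exon. MAP1LC3B (ENSG00000140941.14), the LC3B gene of the autophagosome membrane, fell to 0.372 (0.281 to 0.490) in the control line and 0.189 (0.133 to 0.262) in the knockdown line (log2 fold change -1.89, SE 0.28, adjusted p 3.34e-08). An exon of MAP1LC3B on chromosome 16, 87383995 to 87384196, holds a methionine tRNA gene at 87384022 to 87384094, and the counts do not separate reads of both. It was the 1 called member of 36 autophagy genes, whose medians were 0.23 and 0.09. MIR4521, a microRNA gene next to a serine tRNA gene, fell by 4.44 (SE 0.61), from 47 to 3 counts in the control line and from 63 to 1 in the knockdown line. Its annotated exon on chromosome 17, 8186945 to 8187004, overlaps only the end of that tRNA gene at 8186866 to 8186947. CTC1, a telomere replication gene, and LIMD1-AS1, a long noncoding RNA gene, fell by 1.57 and 1.35 and also have exons that overlap tRNA genes. NDUFC2, a subunit gene of respiratory complex I, fell by 3.20 (SE 0.64, adjusted p 0.000433); it went from 34 to 0 counts in the control line, at least 12-fold lower, and from 34 to 6 in the knockdown line. RNF103, a ubiquitin ligase gene, fell by 2.84 (SE 0.68), TMEM41B, a lipid scramblase gene needed for autophagosomes, by 1.56, TGFBR2, a receptor gene for TGF-beta, by 0.91, and TMBIM6, an endoplasmic reticulum gene that opposes BAX, by 0.84. The mitochondrial tRNA genes MT-TL1, MT-TF and MT-TP fell by 2.05, 2.02 and 1.52, and MT-ND1, a complex I gene of the mitochondrial genome, by 0.60.

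**Figure D1:**
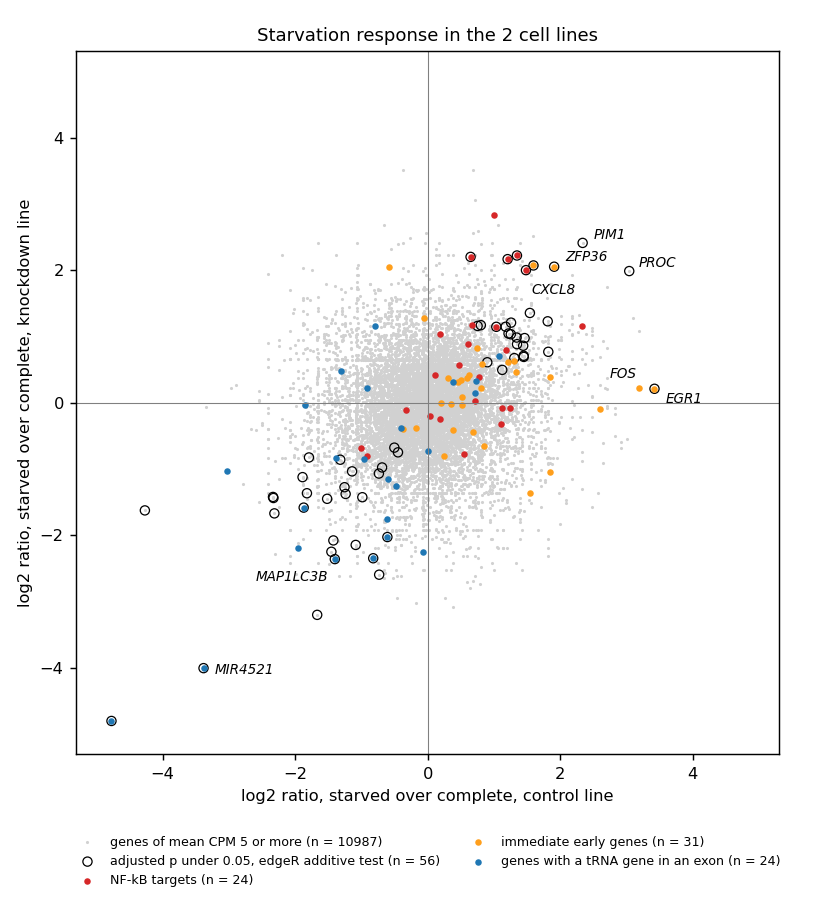
Each point is a gene; the axes give the log2 ratio of starved over complete medium in the control line (x) and in the knockdown line (y), 1 library per group. NF-kB targets lie mostly in the upper right (15 of 24 positive in both lines), and EGR1 and FOS lie far right near 0 on the y axis. MAP1LC3B and MIR4521, which have an exon that overlaps a tRNA gene, lie in the lower left.

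Targets of ATF4, the transcription factor of the amino acid response, had medians near those of random lists. ATF4 itself was at 0.967 (0.737 to 1.27) and 1.05 (0.778 to 1.41) of its level in complete medium. The 36 tested members of its list had medians of -0.02 and -0.09, at percentiles 47.2 and 41.0, and none was called, also when adjusted over the list alone. ASNS, the asparagine synthetase gene, had 0 counts in 3 libraries and 1 in the fourth, and DDIT3, the CHOP gene, 1 to 3 counts, so no fold could be had at this depth. The composition of the starvation medium is not given, so the ratios do not separate a loss of amino acids from a change in serum or other components. GDF15, a stress-induced cytokine gene, had log2 ratios of 0.84 and 0.71 (adjusted p 0.284). The 19 amino acid transporters had medians of -0.28 and -0.46 (percentiles 5.64 and 2.03): none was called, and 4 were lower when adjusted over the list alone. SLC7A1, the arginine and lysine carrier gene and one of the 4, had log2 ratios of -0.43 and -1.42. The 21 unfolded protein response genes had medians of -0.50 and -0.38 (percentiles 0.02 and 3.12), with 17 negative in both lines and 4 lower when adjusted over the list alone, HSPA5 and SYVN1 among them. HSPA5, the BiP chaperone gene, had log2 ratios of -0.52 and -0.89 (adjusted p 0.15), and SYVN1, a ubiquitin ligase gene of protein quality control, -0.82 and -1.64 (adjusted p 0.0799). The 35 lysosome genes had medians of -0.20 and -0.39, with 1 lower when adjusted over the list alone.

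Other lists of nutrient and death genes had no called gene for starvation. Medians in the control and knockdown lines were -0.11 and 0.08 for 20 aminoacyl tRNA synthetases, -0.09 and 0.08 for 18 serine, glycine and one-carbon enzymes, 0.04 and 0.43 for 18 genes of the methionine cycle, 0.02 and -0.26 for 28 MTORC1 pathway genes, and 0.31 and -0.01 for 20 FOXO targets. For 30 p53 targets they were -0.08 and 0.11, and for 16 BCL2 family genes 0.22 and -0.10, where BBC3, the PUMA gene, had log2 ratios of 1.37 and 1.07 (adjusted p 0.203) and passed when adjusted over the list alone. The other scalings turned the sign of a list's median for 4 of 37 lists in the control line and for 10 in the knockdown line. The mean and the median of a list had opposite signs for 5 and 3 lists.

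By the size rule, 589 genes were higher and 572 lower after starvation in the control line, and 577 and 678 in the knockdown line. In simulation, genes not changed gave 713 calls in either direction for the control line and 743 for the knockdown line. Higher in both lines were 42 genes where independent pairs would share 22.9, and lower in both 56 against 26.1, while 49 passed in opposite directions. Across 7401 genes of mean CPM 20 or more, which are not independent replicates, both lines' ratios correlated with Pearson's r of 0.165 and Spearman's rho of 0.165. The genes so named but not called by the additive test had low counts: NRBP2, EMC2, LRRC45, CEP19, FAM201A and DNAH14 were higher, on at most 21 counts per library, and CLCN4, A4GALT, HEXIM2, PINK1, CBX8, DECR2 and MFSD4B lower, with adjusted p-values from 0.0591 for CLCN4 to 0.538 for CEP19. PINK1, the mitophagy kinase gene, went from 6 and 10 counts to 0 in both lines, at least 2.12-fold and 2.15-fold lower. The additive test called 28 genes higher and 28 lower, and 1035 genes had an unadjusted p under 0.05. All 56 had the same sign in both lines, which is no replication, because the test selects genes on both lines together. Of the 56, 32 passed the size rule in both lines, 20 in 1 line and 4 in neither. Limma-voom called 0 genes (840 at an unadjusted p under 0.05), DESeq2 10 and a fit without the block 19. With total counts in the knockdown line, 725 genes were higher and 533 lower by the size rule, and with the deposited TPM 429 and 787.

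The knockdown line had higher median levels of cholesterol and fatty acid synthesis genes than the control line in both media, except for the fatty acid list under starvation with the deposited TPM (-0.01). SCD (ENSG00000099194.6, chromosome 10, 100347124 to 100364834) was 2.87-fold higher (2.74 to 3.01) in complete medium and 2.55-fold higher (2.40 to 2.7) under starvation, from 2221 and 8655 counts in complete medium. SREBF1, the gene of the lipogenic factor SREBP1, rose 2.84-fold (2.47 to 3.27) and 1.57-fold (1.33 to 1.85), and SQLE and HMGCS1, enzyme genes of sterol synthesis, 2.43-fold and 2.14-fold in complete medium and 2.17-fold and 2.14-fold under starvation. The epithelial cadherin gene CDH1 rose 3.79-fold (2.84 to 5.12) and 2.79-fold (1.97 to 4.02), while VIM, the gene of the mesenchymal filament vimentin, fell to 0.276 (0.208 to 0.364) and 0.230 (0.170 to 0.306). In the additive test the log2 fold changes were 1.43 (SE 0.16, adjusted p 9.94e-16) for SCD, 1.08 (SE 0.22, 0.000365) for SREBF1, 1.71 (SE 0.29, 1.97e-06) for CDH1 and -1.98 (SE 0.27, 1.3e-09) for VIM. Each genotype is 1 stable line, so these values compare 2 lines, and a difference that predates the knockdown is not excluded.

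Of 26 cholesterol (SREBP2) targets, 5 rose in the knockdown line, none fell and 21 were not called; adjusted over the list alone, 12 rose and 1 fell. The list's median was 0.40 in complete medium and 0.57 under starvation, at percentiles 99.65 and 100. With the deposited TPM the medians were 0.03 and 0.16, at percentiles 99.73 and 100. Against lists not matched on expression, its percentile in complete medium was 97.33. The 13 fatty acid synthesis genes had medians of 0.72 and 0.41, at percentiles 99.99 and 99.2 (92.51 under starvation against lists not matched on expression). With the deposited TPM their medians were 0.345 and -0.01, at percentiles 99.95 and 99.56. SCD was the 1 called member, and 5 rose when adjusted over the list alone. ABCA1, a cholesterol exporter gene, rose by 1.24 (SE 0.29, adjusted p 0.00483). All 13 mitochondrially encoded messages had positive ratios in both media, with medians of 0.55 and 0.33 (percentiles 99.5 and 97.4), the second -0.10 with the deposited TPM; MT-CYB, MT-ND3, MT-ND4 and MT-ND5 rose, and 10 rose when adjusted over the list alone. After starvation the same 13 messages had medians of -0.22 and -0.48, with MT-ND1 called and 5 lower when adjusted over the list alone.

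The highest ratios in the knockdown line were of genes hardly detected in the control line. GFRA1, a co-receptor gene for glial cell line-derived neurotrophic factor, had 0 and 1 counts in the control line and 29 and 13 in the knockdown line, at least 7.12-fold higher in complete medium and 15.8-fold (2.37 to 671) under starvation. ABCB1, the gene of the drug efflux pump P-glycoprotein, had 0 counts in both control libraries and 13 and 10 in the knockdown line, at least 3.19-fold and 4.05-fold higher. FAT3, a protocadherin gene, NPTX1, a neuronal pentraxin gene, SESN3, a sestrin gene, GALNT6, a glycosyltransferase gene, PATJ, a tight junction gene, and the small nucleolar RNA SNORD13 rose by 3.79, 3.46, 3.77, 3.77, 3.31 and 3.15 on the log2 scale. SESN3 was the 1 called gene of the ATF4, FOXO and MTORC1 lists for the knockdown, each with 2 when adjusted over the list alone. TM4SF4, a tetraspanin-like gene, rose 8.75-fold (5.16 to 16.0) and 4.07-fold (2.44 to 7.08). SLC2A3, a glucose transporter gene, rose by 2.30 (SE 0.56, adjusted p 0.0108), the 1 called gene of 21 in glycolysis. NTRK3, a neurotrophin receptor gene, rose by 2.04, C3, the complement gene, by 1.45, and NEAT1 and MALAT1, nuclear long noncoding RNAs, by 1.41 and 1.06.

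Lower in the knockdown line were CRIP2, a LIM domain gene (log2 fold change -2.96, SE 0.64), SLC16A6, a monocarboxylate transporter gene (-2.63, SE 0.48), INHBB, an activin subunit gene (-2.39, SE 0.46), SSR2, a translocon gene (-2.29, SE 0.36), and CDCP1, a transmembrane SRC substrate gene (-2.20, SE 0.37). RRAD, a small GTPase gene, fell by 2.65 (SE 0.68), CD70, a ligand gene of the TNF family, by 2.01, F2RL1, a protease-activated receptor gene, by 1.75, and FOXM1, a transcription factor gene of dividing cells, by 1.68. MT2A, a metallothionein gene, fell by 1.60, CXCL5, a chemokine gene, by 1.21, CTSB, the lysosomal cathepsin B gene, by 0.94, and DKK1, a secreted WNT inhibitor gene, by 0.95. EGR1 fell by 3.89 (SE 0.95, adjusted p 0.0108), which rests on 42 counts in the starved control library against 1 in the starved knockdown library. Of 19 mesenchymal genes VIM and ITGA5, an integrin gene for fibronectin, fell and 17 were not called, while FN1, the fibronectin gene, had log2 ratios of 1.48 and 0.11. Adjusted over the list alone, 1 mesenchymal gene rose and 2 fell, and the medians were -0.02 and -0.51. CDH1 was the 1 called gene of 12 epithelial and alveolar genes, with medians of 0.23 and -0.03, the first -0.06 with the deposited TPM.

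**Figure D2:**
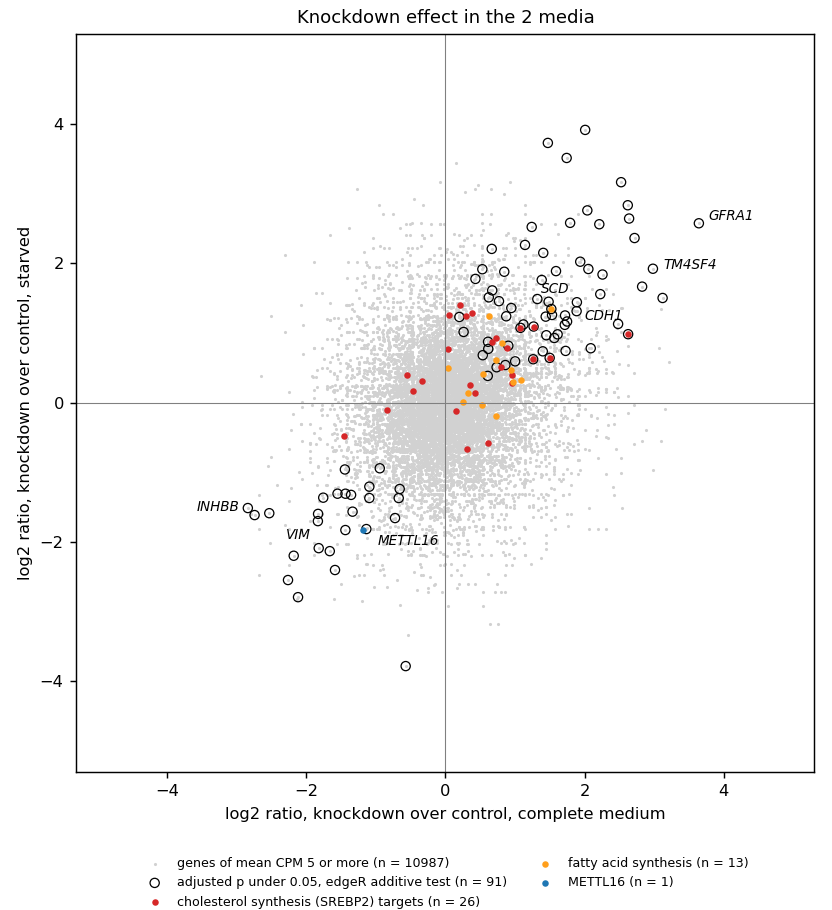
Each point is a gene; the axes give the log2 ratio of the knockdown line over the control line in complete medium (x) and under starvation (y), 1 library per group. Cholesterol and fatty acid synthesis genes lie mostly in the upper right (18 of 26 and 11 of 13 positive in both media), and METTL16 and VIM lie in the lower left.

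Cell cycle lists held no called gene for the knockdown. The 24 S phase genes had medians of -0.28 and -0.31 (percentiles 0.80 and 2.52), negative in both media for 14 genes and positive in both for 0. The 16 replication-dependent histone genes had medians of -0.41 and -0.22, and the 26 genes of G2 and M phase -0.12 and -0.07. Medians were 0.13 and -0.04 for 21 U6-associated spliceosome proteins and 0.15 and -0.09 for 18 SR proteins and splicing kinases. The methionine cycle had medians of -0.33 and -0.08, at percentiles 0.62 and 29.7. Its starvation median in the knockdown line, 0.43, lay at percentile 99.75. That value and -0.33 share 1 library, the knockdown line in complete medium, so they are not separate observations. BAD, a pro-apoptotic BCL2 family gene, had log2 ratios of 1.37 and 1.38 (adjusted p 0.176) and passed when adjusted over the list alone.

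Small nuclear RNAs made up a larger share of the counts in the knockdown line. Their share was 1.52% and 1.71% of counts in the control line in complete medium and starved, and 2.57% and 4.05% in the knockdown line. Summed over all small nuclear RNAs, the log2 ratio of knockdown over control was 0.95 (0.91 to 0.98) in complete medium and 1.32 (1.28 to 1.36) under starvation. U6, the methylation target of METTL16, had ratios of 0.30 (0.16 to 0.44) and 0.63 (0.45 to 0.81), U2 of 0.21 (-0.02 to 0.45) and 0.74 (0.51 to 0.97), U1 of 1.66 and 1.14, U4 of 0.65 and 1.44, and U5 of 0.74 and 2.03. The additive test called 14 small nuclear RNA genes higher in the knockdown line and none lower, among them 5 of U5 and 6 of U1 or its variants. U1 RNA was also higher after starvation, by 1.24 (1.16 to 1.32) in the control line and 0.72 (0.67 to 0.76) in the knockdown line. U6 had starvation ratios of -0.64 (-0.82 to -0.47) and -0.32 (-0.46 to -0.17). MAT2A and U6 were measured as levels; their methylation was not measured in these libraries.

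**Figure D3:**
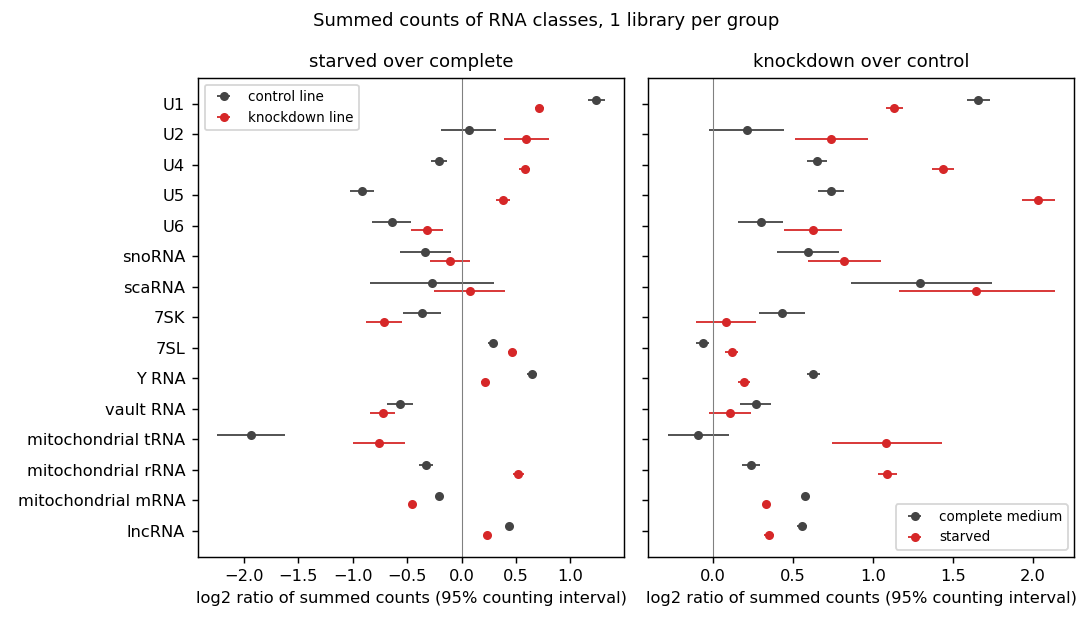
Points give log2 ratios of summed counts per RNA class and bars their 95% counting intervals, for starved over complete medium in each line (left) and knockdown over control in each medium (right), 1 library per group. U1, U4, U5 and U6 lie above 0 in both media in the right panel, the bar of U2 in complete medium includes 0, and vault RNA and mitochondrial tRNA lie below 0 in both lines in the left panel.

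By the size rule, 734 genes were higher and 513 lower in the knockdown line in complete medium, and 744 and 700 under starvation. In simulation, genes not changed gave 717 calls in either direction in complete medium and 696 under starvation. Higher in both media were 94 genes against 36.8 for independent pairs, and lower in both 67 against 24.2, while 50 passed in opposite directions. Genes named by this rule that the additive test did not call were PPARGC1A, a coactivator gene of mitochondrial biogenesis with 0 counts in the control line and 8 and 10 in the knockdown line, and RMND1, EDIL3, CACNA1B and ANXA10, which were lower. The additive test called 65 genes higher and 26 lower, and 1024 genes had an unadjusted p under 0.05. All 91 had the same sign in both media, which again is no replication, because the test selects genes on both media together. Of the 91, 56 passed the size rule in both media, 27 in 1 medium and 8 in neither. Limma-voom called 0 genes (800 at an unadjusted p under 0.05), DESeq2 32, and a fit without the block 50. The direction of the counts depends on the scaling: with total counts 483 genes were higher and 813 lower in complete medium, and with the deposited TPM 456 and 743 in complete medium and 428 and 1025 under starvation. The additive test with total counts called 49 genes higher and 42 lower. Relative to TMM, the median of all genes moved by -0.15 with total counts in complete medium and by -0.38 in complete medium and -0.42 under starvation with TPM; for starvation in the knockdown line it moved by -0.10 with TPM.

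The design also sets the starvation response of the knockdown line against that of the control line. By the size rule for a difference, 688 genes had a higher and 797 a lower ratio in the knockdown line, 1485 in total. Genes not changed gave 1357 such calls in either direction in the simulation of a starvation effect and 1375 in that of a knockdown effect. Both simulations took their spread from the additive fit, whose residual is this difference. They therefore cannot decide whether the lines differ beyond noise. Immediate early genes had a median difference of -0.43, at percentile 1.52 of random lists matched on expression and 7.53 when lists were also matched on gene length and GC content. Also beyond the percentile limits were mesenchymal genes, with -0.68 (percentile 0.54), and amino acid transporters, with -0.485 (1.6). Ribosomal protein genes, with 0.095 (99.84), and nuclear genes of oxidative phosphorylation, with 0.20 (97.53), lay beyond them the other way. NF-kB targets differed both ways, with a median difference of 0.11 (percentile 88.7) and a mean of -0.003. By the size rule CXCL2 had a higher ratio in the knockdown line, by 1.55, and NFKB1, NFKB2 and ICAM1 a lower one, by 1.21, 1.32 and 1.32. The difference has no residual degree of freedom and was not tested.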

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

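Of the tests in this part, the matching on gene length and GC content and the question of a single dish were planned before the result was seen; the other tests were chosen after it.

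Genes that passed the size rule in opposite directions drew attention: 49 for starvation in the control and the knockdown line and 50 for the knockdown in complete medium and under starvation. The numbers expected from independent pairs are 26.9 and 22.2 for the 2 kinds of opposite move under starvation and 34.6 and 25.7 for the knockdown, so neither total lies above what independent pairs with these numbers of calls would give. In simulation 34 and 20 genes not changed passed in opposite directions, fewer than the 49 and 50 seen, and the differences were not tested. The genes named by the largest differences had few counts. The starvation ratio (log2, knockdown minus control) differed by 4.34 (2.19 to 11.1) for ACVR2A, an activin receptor gene with 8 and 0 counts in the control line and 3 and 12 in the knockdown line. It differed by 3.74 for AFAP1L1, an actin-binding gene, and by 3.43 for TRNT1, which encodes the enzyme that adds CCA to tRNAs. It differed by -4.05 for JAG2, a Notch ligand gene, by -3.82 for PALM, the paralemmin gene, and by -3.64 for SCRN3, the secernin 3 gene. POU2F2, KLHL29, WNT3 and SETDB2 had differences of 4.06, 3.91, 3.46 and 3.42, and PAN2, TMEM9B-AS1, SEMA4G, TFR2 and MSC-AS1 of -4.13, -4.01, -3.95, -3.93 and -3.88, where every one of these except SEMA4G has a library with 0 counts. None of these differences was tested.

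Immediate early genes had higher starvation ratios in the control line than in the knockdown line, with medians of 0.68 and 0.22. Their median knockdown ratio was 0.32 in complete medium (percentile 97.58) and -0.37 under starvation (percentile 0.51). A higher level in the knockdown dish in complete medium therefore enters the difference, as does a lower level in the starved knockdown dish. EGR1, FOS and IER2 are among the members that differ most, while BTG2 differed by 2.62 and NR4A2 by 1.34 the other way; by the size rule for a difference 1 member, BTG2, had a higher ratio in the knockdown line and 7 a lower one. Whether the knockdown dish was starved of amino acids is not settled by the NF-kB targets. They lay at percentile 99.99 of random lists in that line, so the dish labelled starved differed from the dish in complete medium. These genes do not measure a loss of amino acids, and ATF4 targets lay at percentiles 47.2 and 41.0 in the control and knockdown lines. Gene length or GC content may account for the size of the difference: the median difference of -0.43 lay at percentile 7.53 among lists matched on expression, length and GC content. Handling of a single dish cannot be told apart from an effect of METTL16, because each group holds 1 library. An effect of the METTL16 knockdown on the response stays open and untested.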

How the results depend on the processing

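Counts thinned to the smallest total, widened intervals and total counts in edgeR were tests chosen after the result was seen; the other alternatives were planned. Under the alternatives 79 values stayed on their side of the threshold or, for counts, within 1.5 times the main count. Another 19 counts moved further and 3 list medians lost their percentile limit. Some of the 79 could not move: leaving out the filter on mean CPM gave the main size rule counts again. Genes below a mean CPM of 1 have too few counts to pass that rule. No METTL16 ratio and no list median over both pairs in these rows changed sign; within 1 medium, the fatty acid synthesis median under starvation went from 0.41 to -0.01 with the deposited TPM. The counts add higher and lower genes, whose balance turned with the scaling. For the knockdown in complete medium, 734 genes higher and 513 lower became 483 and 813 with total counts and 456 and 743 with the deposited TPM, and under starvation 744 and 700 became 659 and 855 and 428 and 1025. In both media 94 and 67 became 66 and 104 with total counts and 49 and 139 with TPM. For starvation in the knockdown line 577 and 678 became 725 and 533 with total counts and 429 and 787 with TPM, in both lines 42 and 56 became 32 and 73 with TPM, and for the difference 688 and 797 became 842 and 636 with total counts.

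With a 1.5-fold size threshold, 1898 genes passed for starvation in the control line, 2147 in the knockdown line and 1967 for the knockdown in complete medium; 315 and 365 passed in the same direction in both pairs for starvation and for the knockdown. With intervals widened by the dispersion of the additive fit, 662, 704, 706, 832 and 633 genes passed for starvation in the control line, starvation in the knockdown line, the knockdown in complete medium, the knockdown under starvation and the difference, and 58 and 92 in both pairs. Fewer genes pass a wider interval by construction. In place of edgeR, DESeq2 called 10 genes for starvation and 32 for the knockdown, all among the genes edgeR called, and limma-voom 0 and 0, with 840 and 800 at an unadjusted p under 0.05. Without the block 19 and 50 genes were called, and at a threshold of 0.10 the knockdown had 145. The cause of the differences between tools was not tested. Against random lists not matched on expression, the median over both lines of the immediate early genes stayed at 0.482 but its percentile in the knockdown line was 96.52; the cholesterol list, at 0.656, and the fatty acid list, at 0.634, had percentiles of 97.33 in complete medium and 92.51 under starvation. Totals ran from 465303 to 775676 counts, with 1 library per group. In simulation at these totals, 16% and 9% of genes changed 2-fold were called for starvation and for the knockdown, and 83% and 85% of genes changed 4-fold. No other depth was simulated, so a limit set by depth is not separated from one set by the lack of replicates. No library could be left out, because no group has a replicate.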

Other observations

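The tests on hosts of tRNA genes and on small nuclear RNAs were chosen after the result was seen; the gene lists were fixed before.

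Some gene groups not yet described for each line and medium lay apart from random lists in 1 line or medium. The 76 ribosomal protein genes had a median starvation ratio of 0.05 in the control line and 0.21 in the knockdown line (percentiles 91.4 and 100) and knockdown ratios of -0.15 and -0.01 (percentiles 0 and 40.5), with none called. The 34 nuclear genes of oxidative phosphorylation had starvation ratios of -0.07 and 0.21 and knockdown ratios of -0.17 and 0.00, with none called. For both lists, starvation in the knockdown line and the knockdown in complete medium share 1 library, the knockdown line in complete medium. Their ratios of opposite sign are therefore not separate observations. Glycolysis genes had starvation ratios of 0.40 and -0.04 (percentiles 99.6 and 57.5). The 20 hypoxia targets had knockdown ratios of 0.44 and 0.18, where DDIT4, an inhibitor gene of MTORC1, passed when adjusted over the list alone. The 26 NRF2 targets, which act against oxidative stress and are high in A549 cells, had starvation ratios of 0.22 and 0.04 (percentiles 98.5 and 83.5) and knockdown ratios of 0.31 and 0.18 (percentiles 97.25 and 93.9), with 3 higher in the knockdown line when adjusted over the list alone. The 25 interferon-stimulated genes had knockdown ratios of 0.52 and 0.15 (percentiles 98.1 and 74.2). The 33 ribosome biogenesis genes, with knockdown ratios of 0.10 and -0.03, and the 17 heat shock genes, with -0.15 and 0.05, stayed inside the percentile limits in every line and medium. With the deposited TPM, the sign of the knockdown median turned for 18 of 37 lists in complete medium and 14 under starvation, among them NRF2 targets in both media and hypoxia targets under starvation.

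Most markers of other cells had few or no counts. None of 9 endothelial markers and 2 of 14 immune markers were tested. The 5 tested fibroblast markers had knockdown ratios of 0.52 and 0.10, and the 5 kidney markers -0.50 and -1.21, with none called. ENO2, the kidney marker with the most counts in the control line, had 6 to 26 counts per library, and FBLN1 among the fibroblast markers 31 to 77.

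Genes lower after starvation in both lines include hosts of tRNA genes. Among the 28 called genes 6 have an exon that overlaps a nuclear tRNA gene, where 0.046 would be expected, and these hosts include MAP1LC3B and CTC1. Lower recovery of all short RNAs alike in the starved libraries is argued against by Y RNA, whose log2 starvation ratio has a lower limit of 0.178 in the line where it is lower, while vault RNA had ratios of -0.57 and -0.73 in the control and knockdown lines. Lower recovery of RNAs as short as tRNA in the starved libraries is a candidate explanation: mitochondrial tRNA had ratios of -1.93 and -0.76 with upper limits of at most -0.518, below mitochondrial mRNA at -0.21 and -0.46. Reads of tRNA genes counted to the genes whose exons overlap them are another candidate, which does not exclude the first. The 18 hosts not called had median ratios of -0.61 and -0.55, at percentiles of at most 1.19. Of these 18, 10 were negative in both lines, while POLG-DT, with ratios of 1.08 and 0.71 (adjusted p 0.0847), and DPP9, with 0.71 and 0.14, were positive in both. So were RP11-108M9.3, with 0.74 and 0.33, and RP4-671O14.6, with 0.39 and 0.31 on 1 to 2 counts per library. Not every host therefore goes with this explanation. A fall of the host messages themselves, and a fall of tRNA levels during starvation, stay open, and the strand of the reads was not given.

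Small nuclear RNAs, summed, were higher in the knockdown line in both media, where U2 in complete medium had an interval that includes 0. Higher recovery of all short RNAs alike in the knockdown libraries is argued against, for the sum, by vault RNA and 7SL RNA. Their knockdown ratios had upper limits of at most 0.367 against 0.95 and 1.32 for small nuclear RNAs. In complete medium this does not hold for U6 (0.30, 0.16 to 0.44) or U2 (0.21), which lay near vault RNA (0.27, 0.17 to 0.37). Under starvation U6 (0.63) and U2 (0.74) lay above vault RNA (0.11). Other short classes were higher: Y RNA by 0.63 and 0.20, small nucleolar RNA by 0.60 and 0.82 and Cajal body RNA (scaRNA) by 1.29 and 1.64, so higher recovery of some short RNAs stays open. Weaker removal of RNAs without a poly(A) tail was looked for in replication-dependent histone messages, which were not higher. Their summed ratios were -0.32 and -0.21 with upper limits of at most -0.116. This cannot decide the question, because these messages also depend on S phase, and the S phase genes had medians of -0.28 and -0.31. Weaker removal therefore stays open. A larger share of nuclear RNA in the knockdown libraries cannot be told apart from higher levels of these RNAs: MALAT1 and NEAT1 were higher in both media, but 7SK had a lower limit of -0.105 under starvation. A role of METTL16, which methylates U6, stays open and was not tested.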
